A study of Mus musculus with 9 samples.

How the data were processed

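The series profiled 7 histone acetylations (H3K9ac, H3K14ac, H3K18ac, H3K23ac, H3K27ac, H4K8ac and H2AK5ac) and H3K4me3, with an IgG control, in lung endothelial cells of wild-type mice. The assay was ACT-seq, in which an antibody directs a Protein A/G-Tn5 transposase to the chromatin that carries its mark and the transposase cuts and tags the DNA there. Per the labels' protocols, libraries were amplified by PCR, selected for size and sequenced as paired ends. Each of the 9 targets had 1 library, so no value has a replicate error, no test between marks was run and no p-value is given.

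The authors deposited 1 table of read counts for 578465 region identifiers in 9 libraries. Per the file headers, the counts were made by featureCounts 2.0.6 from a region file, with the paired-end option, without strand, without counting read pairs as 1 fragment, and without the option that lets a read count for several regions. Under these options each mate of a pair is a count of its own, and a read that overlaps regions of more than 1 identifier is discarded. The submitters' processing notes name FastQC, MultiQC, Trim Galore, STAR, MACS2, featureCounts and DESeq2, and the genome builds mm10 and GRCm38.p6. The settings of the aligner and the peak caller, the treatment of PCR duplicates, and the use of IgG in peak calling are not given in the sources used here. STAR was written for spliced RNA reads, and the table lists regions on 228 reference sequences, unplaced contigs among them.

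The table's 578465 identifiers hold 1309635 regions, because 8 region lists, each numbered from 1, had been joined under shared names. Of the identifiers, 398202 hold 1 region and 180263 hold more than 1. In 180258 of the latter the regions lie on more than 1 reference sequence, so the count of such an identifier is a sum over unrelated places. The smallest start in the table is 0, so starts were read as counted from 0, and positions are given here counted from 1.

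The lists were separated again by assigning the regions of each identifier so that every list runs in genome order and holds no region under its commonest width. With order alone, 0 identifiers broke the constraint, and with width added 8 did. On simulated lists, 99.9% of 91140 regions under shared identifiers returned to their own list, and 98.6% did with order alone. These lists were smaller, lay at random places and shared 1 rate of regions at the commonest width. In the data this rate ran from 20.0% to 80.9% between lists, so the accuracy there may differ. For every region the bases covered by no region of another identifier were counted (unshared bases), and on 3000 simulated regions 0 differed from a count base by base. The reads per kb of unshared bases of each list were estimated in each library by non-negative least squares over identifiers, without mitochondrial and contig identifiers. The largest error on simulated data was 3.30% over 20000 identifiers. Each list is named by the library with the highest depth-scaled density in it, for example "H3K27ac-rich list". This is a measured property of the list and not a record of how it was called.

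Genes were taken from an NCBI RefSeq table of GRCm38.p6, the build in the processing notes, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table used here has no strand. Windows of 2 kb either side of both gene ends were therefore used in place of the window around the 5' end that had been fixed beforehand. Exons, introns and UTRs were not used here. For each gene and list, the bases of the windows covered by peaks were summed, and the number of lists (of 8) with at least 1 covered base was counted. The 22 gene lists, the rule for named genes and the alternatives to be tried were fixed before the data were examined. The use of peak lists in place of counts, with every result on them, the windows at both gene ends and the count against the floor of IgG were chosen after the data were seen, once the shared identifiers had been found. A list's mean is given as its percentile among 10000 random lists of protein-coding genes with as many genes in each of 10 bins of gene length, ties counted as 0.5. Percentiles of 97.5 or more and 2.5 or less are called above and below random lists. On simulated values for 20000 genes, 5.00% of 200 unchanged lists lay outside these limits, and 100% of 200 lists raised by 2 lay above. Percentiles describe these libraries and are no test across genes, which are not independent replicates. Peaks at gene ends were compared with 100 sets of peaks moved around each chromosome by a random distance, assembly gaps included, and overlaps between lists with 20 such sets, with at least 1 shared base.

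Counts were used in 2 ways. First, for all identifiers, log2 CPM (counts scaled to the table total of each library) were taken with a prior count of 2 scaled to library size, and an identifier with at least 10 reads over a mark and IgG was called enriched at 2-fold or more over IgG. A second count replaced an IgG value under 3 reads by the floor of 3 reads, which is 8.20 CPM in the IgG library. On simulated libraries at the H3K4me3 and IgG depths drawn from 1 pooled profile, the rule with the prior count called 15.7% of 42256 unchanged identifiers, and 94.0% and 100.0% of those raised 4-fold and 16-fold. With the floor these shares were 2.10%, 95.0% and 100.0%. The IgG library of the series was 0 in 97.1 to 99.8% of tested identifiers, and the simulated one was not so uneven. The simulated shares are therefore not error rates of the calls made here, and the depths of the other marks were not simulated. Second, reads were placed on the genome only for the 381466 identifiers with unshared bases in exactly 1 region (placeable reads). A gene's reads are the sum over such regions that overlap its windows. Level over IgG is the median log2 ratio over a list's genes, with random lists matched on the IgG level, and specificity is the median of a mark's log2 CPM minus the mean of the other 7 marks, with random lists matched on the mean of the 9 libraries. Similarity is the Spearman correlation of log2 CPM across regions with at least 10 reads over the 9 libraries.

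Named genes followed a rule. From the endothelial identity list, the 6 with the highest and 3 with the lowest mean log2 ratio to IgG over the acetylations were taken. From every other list, the 2 highest and 1 lowest were taken. Per mark, the 3 with the highest ratio to IgG and the 2 most specific were taken, among genes with at least 50 reads. Slc7a11, Cth, Cbs, Cdo1, Cdh5, Pecam1, Kdr and Erg were named in any case. Genes with 0 placeable reads tie for lowest and were taken in genome order.

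Alternatives were TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors, prior counts of 0.5 and 5, other count minimums, a 4-fold threshold, other windows, other matching of random lists, the median of the other marks, Pearson correlation, ratios to IgG, thinning every library to the shallowest, and leaving out chromosomes X, Y and M. DESeq2 factors rest on 61 identifiers above 0 in every library. Added after seeing the data were identifiers with 1 region, peaks wider than the minimum, lists separated by order alone, gene spans and unmatched random lists for the peak lists, and a 1 kb window for peaks. Intervals of shares are exact binomial (Clopper-Pearson) and of reads exact Poisson, at 95%. They cover counting error only, since PCR copies are not independent molecules and mates are counted apart. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.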

Results

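The chromatin of mouse lung endothelial cells was profiled by ACT-seq for 8 histone marks, with 1 library per mark and 1 for IgG. The series title places these profiles in a study of how cystine uptake and breakdown feed histone acetylation at endothelial genes. Library totals in the count table ranged from 365999 reads for IgG to 10044130 for H3K14ac. H3K23ac had 4803692 reads, H2AK5ac 4201292 and H3K27ac 2533242. H4K8ac had 1750024, H3K9ac 1628294, H3K18ac 1546265 and H3K4me3 1477463. H3K14ac reads were spread over 83.8% of the 578465 identifiers, H3K27ac reads over 59.2% and H3K9ac reads over 4.56%. IgG had reads in 903 identifiers, and 74.2% of its reads lay in its 100 highest. Mitochondrial identifiers held 13.5% of IgG reads (95% interval 13.4 to 13.6%) and at most 0.137% of the reads of any mark (H3K9ac and H3K4me3).

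The table joins 8 peak lists, and each list was densest in the library of a different mark. The H2AK5ac-rich list held 307 H2AK5ac CPM (reads scaled to the library's table total) per kb of unshared bases, the H3K9ac-rich list 284 H3K9ac CPM per kb and the H3K4me3-rich list 178 H3K4me3 CPM per kb. Values were 93.8 for H3K23ac, 81.3 for H4K8ac, 66.8 for H3K18ac, 43.8 for H3K27ac and 13.3 for H3K14ac. The leading mark exceeded the second mark by 2.38 to 24.5 times. Unshared bases were 11.9% (H3K27ac-rich) to 77.0% (H3K14ac-rich) of a list's bases. Places shared with another list, where its mark may also be dense, do not enter these leads. IgG led no list. It came second in the H3K14ac-rich, H3K18ac-rich, H3K27ac-rich, H3K4me3-rich and H3K9ac-rich lists, closest to the leading mark in the H3K27ac-rich list with 22.5. The H3K14ac-rich list was the longest, with 578465 peaks, and the H3K9ac-rich list the shortest, with 48943. The others held 180263 (H4K8ac-rich), 171339 (H3K18ac-rich), 114890 (H3K27ac-rich), 90317 (H3K23ac-rich), 69183 (H2AK5ac-rich) and 56235 peaks (H3K4me3-rich).

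**Figure D1:**
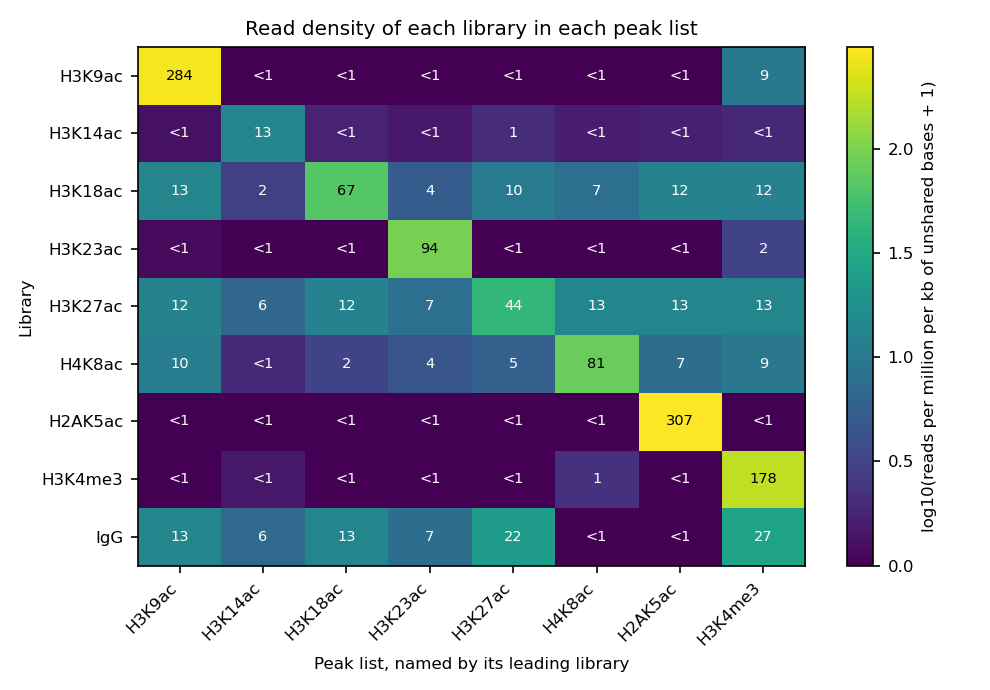
CPM per kb of unshared bases of each library (rows) in each peak list (columns, named by the leading library), with colour on a log10 scale and 1 library per row. The highest value of every column is that of a different mark, from 13.3 for H3K14ac to 307 for H2AK5ac.

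The first comparison asked at which genes the marks lay. Endothelial identity genes carried peaks of most lists: their ends had peaks of 6.97 lists on average ± 2.01 (SD over 32 genes), against 5.06 in random lists matched on gene length, and above all 10000 of these. In 21 of the 32 genes all 8 lists had a peak. Cdh5, which encodes VE-cadherin of endothelial junctions, Pecam1, the adhesion molecule CD31, and Kdr, the main VEGF receptor, were among the 21. Markers of other cells had fewer: 3.74 lists ± 2.92 (19 genes) for lung epithelium, 3.43 ± 2.46 (21 genes) for leukocytes and 3.32 ± 2.21 (19 genes) for mesenchyme. These lie at percentiles 1.84, 0.825 and 0.035 of random lists. Over gene spans, lung epithelium (4.95 lists, percentile 14.2) and leukocytes (4.57, percentile 7.42) fell within random lists, as did lung epithelium with unmatched random lists (percentile 4.55).

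At Cdh5 (gene ID 12562, chromosome 8, 104101613 to 104144504), H3K4me3-rich peaks covered 1900 bp of the windows at the gene ends, H3K23ac-rich peaks 2125 bp, H3K9ac-rich peaks 1610 bp and H3K27ac-rich peaks 1019 bp. The widest H3K27ac-rich peak of Cdh5 lay inside the gene (104121657 to 104122246). Pecam1 (gene ID 18613, chromosome 11, 106654213 to 106715281) had 1457 bp of H3K4me3-rich and 784 bp of H3K27ac-rich peaks at its ends. Its widest H3K27ac-rich peak was also internal, at 106674563 to 106675204. Kdr (gene ID 16542, chromosome 5, 75932827 to 75979072) had 1903 bp of H3K4me3-rich and 1572 bp of H3K27ac-rich peaks. Erg (gene ID 13876, chromosome 16, 95359169 to 95586600), a transcription factor of endothelial cells, had peaks of 6 lists at its annotated ends and 157 bp of H3K4me3-rich peaks there. Over its whole span all 8 lists had peaks, with 3419 bp of H3K4me3-rich and 4491 bp of H3K27ac-rich peaks, the widest of them 95.4 and 95.6 kb from the end of the gene with the lower coordinate and 131 kb from the other.

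Of the endothelial genes named by rule, Egfl7, an angiogenic factor secreted by endothelium, Eng, a TGF-beta co-receptor, Klf4, Tie1, Lyl1, Tal1 and Fli1 had peaks of all 8 lists at their ends. Vwf, von Willebrand factor, had 6, with 0 bp of H3K9ac-rich and H3K4me3-rich peaks. Placeable H3K14ac reads were 80 at Tie1, 81 at Vwf and 65 at Eng, with 0 IgG reads at each. Tal1, Fli1 and Erg ranked lowest by reads, with 16 H3K14ac reads at Tal1, 0 at Fli1 and 44 at Erg. A gene's placeable reads leave out every base shared between lists.

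Arterial genes had peaks of 6.59 lists ± 2.00 (17 genes, percentile 98.1). Jag1 and Efnb2, Notch and ephrin ligands of arteries, had all 8, as did Notch4. With peaks wider than the minimum alone, the arterial list fell within random lists (5.47 lists, percentile 97.4). In covered bases it lay within them for H3K9ac-rich (95.5), H3K27ac-rich (94.4), H4K8ac-rich (92.4) and H2AK5ac-rich peaks (86.0). It lay above for the other peak lists. Lymphatic genes had 6.6 ± 2.12 (10 genes, percentile 96.9), Sema3d and Lyve1 with 7 each and Pdpn with 8. This list was above random lists with wider peaks alone (5.70 lists) and with a 1 kb window (6.40, percentile 98.0). Venous genes had 6.10 ± 1.97 (10 genes, percentile 79.6), from 5 at Vcam1 to 7 at Bmp4 and 8 at Ephb4. Lung capillary genes had 4.73 ± 2.63 (15 genes, percentile 31.0). Plvap, a protein of endothelial fenestrae, had all 8, while Gpihbp1, which holds lipoprotein lipase on capillaries, had 2 and Tbx3 had 5. Angiogenic growth genes had 7.48 ± 1.36 (21 genes) and lay above all random lists. Angpt2, Pdgfb and Myc each had all 8.

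The cystine, cysteine and glutathione list, the pathway in the series title, had peaks of 6.37 lists ± 2.06 (30 genes, percentile 98.4), with all 8 at 14 genes. With peaks wider than the minimum alone it fell within random lists (5.20 lists, percentile 97.1). In covered bases it lay within random lists for all 8 peak lists, from percentile 83.5 (H2AK5ac-rich) to 95.8 (H3K14ac-rich). Txn1, a thioredoxin, and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, had all 8. Slc7a11 (gene ID 26570, chromosome 3, 50364936 to 50499087), the cystine importer, had 104 bp of H3K18ac-rich peaks at its annotated ends and no other list there. Over its span all 8 lists had peaks: 2587 bp H3K9ac-rich, 2807 bp H3K27ac-rich and 2406 bp H3K4me3-rich. Its widest H3K4me3-rich peak lay at 50382002 to 50382970, and its widest H3K27ac-rich peak at 50438079 to 50438523. The named enzymes of cysteine supply and oxidation had fewer than 8 lists at their ends. All 8 lists were present at 31.1% of all protein-coding genes, so this is usual. Cth (gene ID 107869, chromosome 3, 157894248 to 157925081), cystathionine gamma-lyase, had 5 lists and Cbs (gene ID 12411, chromosome 17, 31612623 to 31637233), cystathionine beta-synthase, had 6. Cdo1 (gene ID 12583, chromosome 18, 46713193 to 46728502), cysteine dioxygenase, had 5. H3K4me3-rich peaks covered 703 bp at Cth, 563 bp at Cbs and 985 bp at Cdo1, and H3K27ac-rich peaks 370, 233 and 281 bp. The widest peak at the upper end of Cth also overlaps the neighbouring gene 1810013D15Rik.

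Genes of acetyl-CoA supply had 7.00 lists ± 1.35 (23 genes, percentile 99.6), with Pdha1 and Cpt2 at 8 and Acss2 at 7. Histone acetyltransferases had 7.07 ± 1.49 (15 genes, percentile 99.2), with Ep300 and Gtf3c4 at 7 and Kat7 at 8. Over gene spans the acetyltransferases fell within random lists (7.67 lists, percentile 97.0). Histone deacetylases had 6.56 ± 1.85 (18 genes, percentile 96.5), with Sirt4 at 8 and Hdac7 and Hdac8 at 4. They were above random lists over gene spans (7.72 lists, percentile 99.9). Amino acid and oxidative stress genes had 7.86 ± 0.359 (21 genes), the highest of the 22 lists, with Nfe2l2, Atf4 and Mthfd2 at 8. Housekeeping genes had 7.68 ± 0.894 (22 genes), with Rpl13a, Actb and Rps18 at 8. Immediate-early genes had 7.68 ± 0.749 (19 genes), with Dusp1, Fosl2 and Junb at 8, and cell cycle genes 7.57 ± 0.746 (21 genes), with Ccnd1, E2f1 and Rrm2 at 8. These 4 lists lay above all random lists. Glycolysis genes had 6.44 ± 2.22 (16 genes, percentile 94.6), with Aldoa at 8, Pfkm at 7 and Gpi1 at 6, and were above random lists over gene spans (7.38 lists, percentile 98.8).

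Genes of other lineages had few peaks. Neuronal genes had 3.78 lists ± 2.29 (18 genes, percentile 0.860), developmental transcription factors 2.96 ± 2.06 (28 genes), and liver, pancreas and muscle genes 2.35 ± 2.16 (20 genes). Olfactory receptors had 0.714 ± 0.976 (1110 genes), and 550 of them had none. The last 3 lists lay below all random lists. Hoxd13 had 2 lists, Neurog2 3 and Nkx2-2 4, Cyp2e1 2, Cpa1 3 and Cela1 6. Gad2 had 4 and Camk2a 5, while Syn1 had 8. Among markers of other lung cells, Krt18 had 8 lists, Krt8 7 and Sftpb 4. Csf1r had 4, Coro1a 6 and Itgax 2, Pdgfrb and Tagln had 6 each and Col1a2 had 2. Olfr457 had 6, Olfr876 5 and Olfr524 1. With unmatched random lists, neurons fell within them (percentile 5.39).

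**Figure D2:**
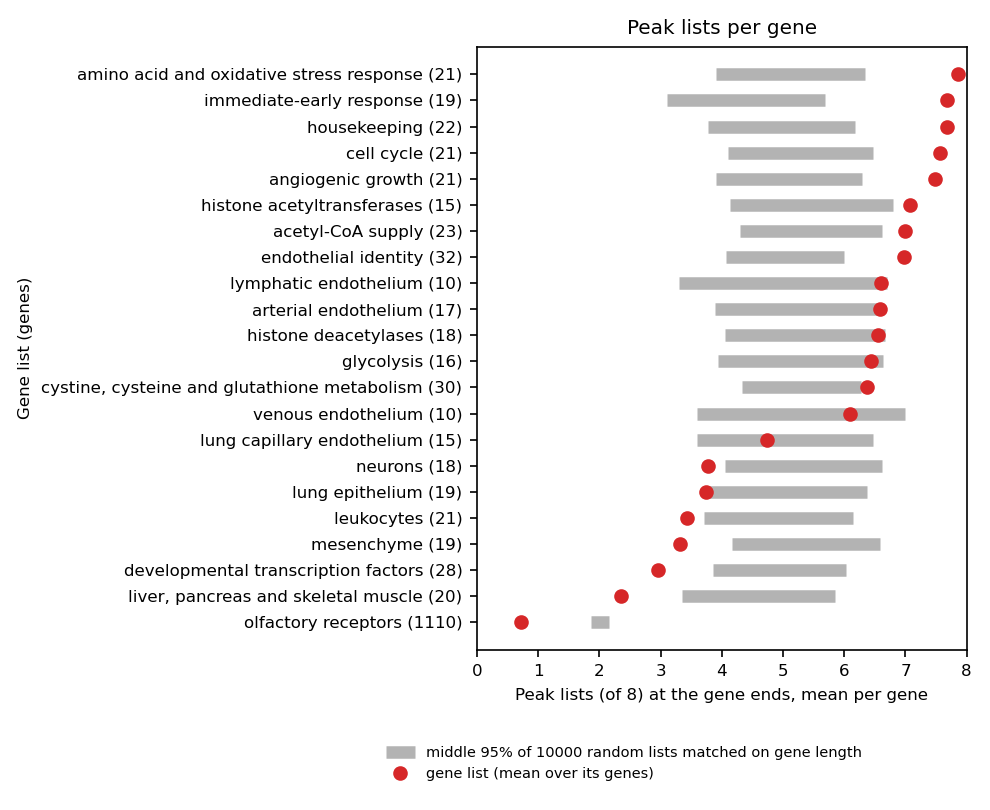
Mean number of peak lists (of 8) with a peak within 2 kb of either gene end, for 22 gene lists (red points, number of genes in brackets), with the middle 95% of 10000 random lists matched on gene length (grey bars). Endothelial identity lies at 6.97 to the right of its bar, and mesenchyme at 3.32 to the left of its bar.

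The second comparison asked how the marks differed between gene groups. Endothelial identity, angiogenic, immediate-early, stress response and housekeeping genes were covered more than random lists by all 8 peak lists (percentiles 98.98 to 100). H2AK5ac-rich peaks covered 318 bp per endothelial identity gene, 3.13 times the mean of random lists. Their ratio was 4.67 at immediate-early, 3.66 at angiogenic growth and 2.68 at amino acid and oxidative stress genes. Housekeeping genes had 1.94 (percentile 98.98). At cell cycle genes the ratio was 1.10 (percentile 64.8), although 14 of the 21 genes had a peak, a share above random lists (percentile 98.01). The ratio was 0.924 at histone acetyltransferases (percentile 45.3) and 0.839 at acetyl-CoA supply (percentile 32.0). Acetyl-CoA genes also lay within random lists in H3K18ac-rich (percentile 96.09) and H4K8ac-rich bases (96.73), and acetyltransferases in H3K14ac-rich bases (93.72). The other 7 peak lists had ratios of 1.40 (H3K14ac-rich) to 2.03 (H3K9ac-rich) at cell cycle genes. At mesenchyme genes H3K9ac-rich peaks had the lowest ratio of the 8 lists, 0.0473, and H3K14ac-rich peaks the highest, 0.714. Differences between peak lists in these ratios were not tested.

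Across all 21887 protein-coding genes, 6803 had peaks of all 8 lists at their ends and 2043 of none. H3K14ac-rich peaks reached the ends of 85.0% of genes, H3K18ac-rich 68.4%, H4K8ac-rich 66.9%, H3K27ac-rich 63.1% and H3K4me3-rich 61.5%. H3K23ac-rich peaks reached 57.4%, H3K9ac-rich 50.3% and H2AK5ac-rich 39.8%. Peaks of a neighbouring gene within 2 kb count for both genes. These shares of genes were not compared with shifted peaks. The H3K14ac-rich list is also the longest, with 578465 peaks, and its peaks lay at gene ends 1.34 times as often as shifted ones.

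**Figure D3:**
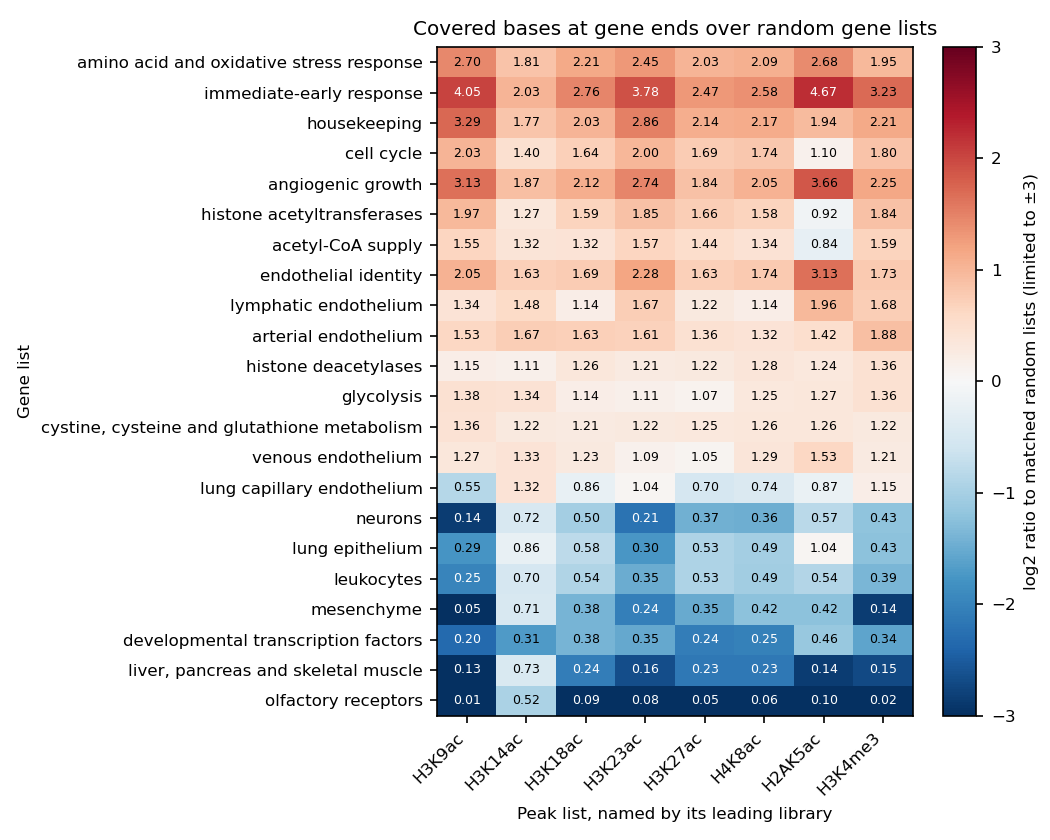
Bases covered at gene ends by each peak list (columns), as the ratio of a gene list's mean to that of matched random lists (printed values; colour is log2, limited to 3 in each direction). H2AK5ac-rich peaks stand at 3.13 for endothelial identity and 0.839 for acetyl-CoA supply.

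The third comparison asked where in the genome the peaks lay. H3K9ac-rich and H3K4me3-rich peaks were concentrated at gene ends, with 35.2% (34.8 to 35.7%) and 31.8% (31.4 to 32.2%) within 2 kb, 5.56 and 5.00 times the shares of shifted peaks. H3K23ac-rich peaks had 23.9% (3.86 times), H3K27ac-rich 20.3% (3.31), H4K8ac-rich 18.5% (3.06), H2AK5ac-rich 17.6% (2.90) and H3K18ac-rich 16.7% (2.76). H3K14ac-rich peaks had 7.91% (7.84 to 7.98%), 1.34 times the shifted share of 5.89%, and 44.6% of them lay outside annotated genes. In every list 0 of 100 shifted sets reached the observed count.

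The excess at gene ends differed with peak width. Of H3K14ac-rich peaks, 80.9% had the minimum width of 138 bp, and these lay at gene ends 1.06 times as often as shifted peaks, against 2.47 times for wider ones. Wider H3K4me3-rich peaks reached 8.30 times and wider H3K23ac-rich peaks 7.26 times, against 2.09 and 2.69 times at minimum width. H2AK5ac-rich peaks were the exception among the 8 lists, with 2.97 times at minimum width and 2.70 times when wider.

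**Figure D4:**
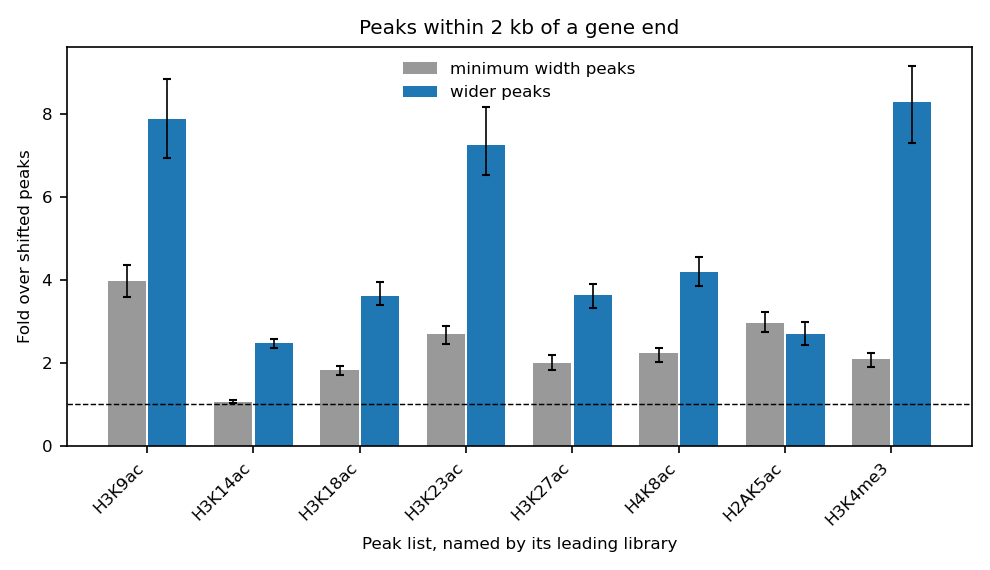
Share of peaks within 2 kb of a gene end over the mean share of 100 shifted peak sets, for peaks at the minimum width (grey) and wider peaks (blue) of each list; bars start at 0, error lines span the folds over the highest and the lowest shifted share, and the dashed line marks 1. Wider peaks exceed minimum-width peaks in 7 of the 8 lists, and H2AK5ac-rich peaks (2.97 and 2.70) are the exception.

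H3K4me3 had 50.6% (50.3 to 50.9%) of its placeable reads at gene ends, H3K9ac 34.3% (33.8 to 34.8%) and H3K23ac 25.2% (24.9 to 25.6%). H4K8ac had 14.3%, H3K18ac 10.2%, H2AK5ac 10.03%, H3K27ac 7.51% and H3K14ac 4.74%, while IgG had 10.7% (10.5 to 10.9%) and the unshared bases themselves 5.08%. The IgG reads lay in 278 placeable regions, 19 of them at gene ends. By region this was 1.22 times the share of all placeable regions (interval 0.744 to 1.87). The interval of IgG reads leaves out this clustering, so it does not rank IgG against H3K18ac, H2AK5ac, H3K27ac or H3K14ac. Placeable reads were 68.9% of the H3K14ac library but 1.32% of H3K23ac, 1.55% of H2AK5ac and 1.95% of H3K9ac. Of the placeable regions, 99.0% belong to the H3K14ac-rich list, so the reads of the other 7 marks were measured nearly always inside its peaks. They exclude bases shared between lists and, for the most part, chromosomes 1 and 10 to 13, where 513 of the 11873 genes with placeable regions lie.

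The fourth comparison asked how alike the marks were. Most H3K27ac-rich peaks lay on H3K18ac-rich and H4K8ac-rich peaks: 72.4% overlapped an H3K18ac-rich peak and 67.0% an H4K8ac-rich peak, 25.9 and 23.7 times the shifted values. In the other direction, 49.1% of H3K18ac-rich and 44.1% of H4K8ac-rich peaks overlapped an H3K27ac-rich peak. Of H3K9ac-rich peaks, 64.6% overlapped an H3K18ac-rich and 48.2% an H3K4me3-rich peak, the latter 31.7 times the shifted value. Of H3K14ac-rich peaks, 12.9% overlapped an H4K8ac-rich peak. Of the 819240 merged regions, 82.7% belonged to 1 list, and 6.59% of these, with a mean length of 145 bp, lay at gene ends. The H3K14ac-rich list held 578465 of the 1309635 regions before merging, so it weighs heavily in this share. The 10710 regions of all 8 lists averaged 1015 bp, and 47.1% lay at gene ends. Longer regions can meet a gene end more often by size alone, and merged regions were not compared with shifted ones.

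Correlations of placeable reads across 299263 regions were low. The median Spearman correlation was 0.109 over the pairs of acetylations, 0.186 between acetylations and H3K4me3, and 0.0120 between marks and IgG. Libraries simulated from 1 pooled profile gave 0.127 over the pairs of acetylations and 0.0982 with H3K4me3. H3K18ac with H4K8ac reached 0.339 and H3K18ac with H3K27ac 0.317, while H3K14ac with H3K18ac was 0.0108. As ratios to the shared IgG library the acetylations gave 0.144, against 0.739 in the simulated libraries, and a median covariance of 0.0749 against 1.30. IgG had reads in 278 placeable regions, and the simulated libraries held no IgG this uneven. The simulated ratios are therefore no baseline for the observed ones, and nothing is concluded from the gap. The sign turned when every library was thinned to the shallowest (-0.0026 between acetylations, -0.148 with H3K4me3 and -0.117 with IgG, over 3824 regions). Regions are not independent replicates, and 99.3% of these regions belong to the H3K14ac-rich list, so they were selected on a compared mark.

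The fifth comparison set each mark against IgG. By the fixed rule 393633 of 394426 identifiers were above IgG for H3K14ac, 80349 of 80966 for H3K27ac, 67051 of 67590 for H4K8ac and 60999 of 61540 for H3K18ac. Counts were 49091 of 49603 for H3K23ac, 33856 of 34334 for H3K4me3, 24054 of 24518 for H2AK5ac and 17512 of 17969 for H3K9ac. IgG had 0 reads in 97.1 to 99.8% of the tested identifiers, so these calls rest on the prior count. With a prior count of 5, H3K14ac had 273639. With a minimum of 50 reads fewer identifiers were tested and every mark had fewer, H3K14ac 20577 of 20984 and H3K27ac 2462 of 2823. Against IgG or its floor of 3 reads, 13161 identifiers (73.2%) were at least 2-fold higher in H3K9ac, 14018 (57.2%) in H2AK5ac, 22453 (45.3%) in H3K23ac and 13425 (39.1%) in H3K4me3. H4K8ac had 13347 (19.7%), H3K18ac 10366 (16.8%), H3K27ac 4527 (5.59%) and H3K14ac 38. For H3K14ac at its depth, 165 reads in an identifier would be needed.

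At single genes, the highest values over IgG in placeable reads, all against 0 IgG reads, were those of H3K9ac and H3K4me3. Placeable reads were 1.95% of the H3K9ac and 6.80% of the H3K4me3 library. The ranking therefore covers what lies in unshared bases and is no ranking of all genes by mark. Cttnbp2nl had 398 H3K9ac reads (95% interval 360 to 439), at least 29.8-fold higher than IgG, Dusp1, a phosphatase of the immediate-early response, 261 and Ctps 228. For H3K4me3, Efnb2 had 280 reads (248 to 315), at least 23.1-fold higher, Spry2 266 and Ddi2 247. Osgin1 led H3K18ac with 197 reads (at least 15.5-fold higher), ahead of Cmip with 71 and Efna1 with 70, and led H3K27ac with 131 (at least 6.31-fold higher), ahead of Frmd8 with 100 and 6330409D20Rik with 95. Ptpn1 had 274 H2AK5ac reads (at least 7.96-fold higher), H6pd 255 and Fam210a 242, and Mex3c had 310 H3K23ac reads (at least 7.87-fold higher). Rpl29 and Acy1, which lie within 2 kb of each other, had 304 H3K23ac reads each. For H4K8ac, Ptpa and Angpt2, an angiopoietin that endothelium releases, had 103 reads each (at least 7.18-fold higher) and Id1 96. For H3K14ac, Itgb2l had 309 reads (at least 3.75-fold higher), Speer4a 294 and Col22a1 264.

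By difference from the other marks in placeable reads, C5ar1 (125) and Prp2 (119) were most specific for H3K9ac, and Speer4a and Col22a1 for H3K14ac. Osgin1 and Fblim1 (53) were so for H3K18ac, Mex3c and Rfx1 (152) for H3K23ac, and Hgfac (71) and Angpt2 (55) for H3K27ac. Angpt2 and Phf19 (58) led for H4K8ac, Fam210a and Eva1b (224) for H2AK5ac, and Ift140 (210) and Usp5 (82) for H3K4me3.

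In placeable reads, nearly all inside H3K14ac-rich peaks, the endothelial identity list (24 genes measured) was above random lists in H3K18ac (percentile 100), H4K8ac (99.995) and H3K27ac (99.7). IgG was above 0 at 22 of the 11873 genes measured, so the ratios rest on the prior count and matching on IgG matched almost nothing. The median over all genes was 0 reads in H3K18ac and H4K8ac and 3 in H3K27ac. H3K14ac was at percentile 91.9. In H3K9ac, H3K23ac, H2AK5ac and H3K4me3 the median gene had 0 reads in this list and in all genes, so the list could not be ranked at gene ends. Over gene bodies with 2 kb either side it lay above random lists in H3K14ac, H3K23ac and H3K4me3. These random lists were not matched on gene length, and a longer gene can sum more regions, so length may enter these percentiles. This was not tested. Matched on the mean of the 9 libraries, H3K18ac (percentile 93.8) and H3K27ac (37.9) fell within random lists. So matched, H3K4me3 lay below them, although its median gene had 0 reads. For H3K27ac a 1 kb window also did so (90.1). By specificity, endothelial genes were above random lists in H4K8ac (percentile 99.5) and below in H3K4me3 (1.87), where the median gene had 0 reads, so that value rests on the other marks. With the median of the other marks in place of their mean, H3K4me3 fell within random lists. Over the 22 lists and 8 marks, 16 of 176 pairs lay above random lists in level and 1 below (olfactory receptors in H3K27ac), and 9 above and 13 below in specificity. In H3K9ac, H3K23ac and H2AK5ac the median of each of the 22 lists equalled that of all genes, so no list could be ranked by level there. Level was not high at endothelial genes alone: mesenchyme genes (9 measured) lay above random lists in H3K18ac (percentile 98.6), and by specificity in H3K27ac (98.16, against 45.7 for endothelial genes). The other lists above in level were arterial genes (H3K18ac, H4K8ac), angiogenic genes (H3K27ac, H4K8ac), lung capillary genes (H3K14ac), the cystine list (H3K14ac, H3K27ac, H3K4me3), stress response genes (H3K18ac), immediate-early genes (H4K8ac), and housekeeping and cell cycle genes (H3K4me3). Matched on the mean of the 9 libraries, 5 pairs lay above in level, while over gene bodies with 2 kb either side, not matched on gene length, more than 16 did.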

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

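Of the alternatives in this part, those for peak lists per gene, for folds at gene ends and for identifiers with 1 region were chosen after seeing the data, as were the ranges of 1.5 times for folds and 0.05 for correlations. No paired analysis was possible because each mark has 1 library and no result comes from a test. Of the 300 alternatives, 248 gave values on the same side or within the stated range (1.5 times for counts and folds, 0.05 for correlations), TMM and DESeq2 factors, prior counts, lists separated by order alone and leaving out chromosomes X, Y and M among them. Of the 248, 25 concern the endothelial level in H3K9ac, H3K23ac, H2AK5ac and H3K4me3, where the median of 0 reads left little that could move, so they say nothing about stability. Calls over IgG could also change little under other factors or a smaller prior, since IgG had 0 reads in 97.1 to 99.8% of tested identifiers. The cause was not tested except where the alternative itself sets the number of identifiers or genes.

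Enriched identifiers depended in number on the minimum count, which also sets how many were tested. With a minimum of 50 they were 9859 (H3K9ac), 20577 (H3K14ac), 1838 (H3K18ac), 29849 (H3K23ac), 2462 (H3K27ac), 2780 (H4K8ac), 15955 (H2AK5ac) and 6482 (H3K4me3), and with none 158547 (H3K18ac), 281079 (H3K27ac), 118562 (H4K8ac) and 64602 (H3K4me3). With a minimum of 50, 84.3% (H3K18ac) to 98.8% (H3K23ac) of the identifiers tested were above IgG. With none, the shares were 11.2% (H3K4me3) to 48.6% (H3K27ac) for the marks given. At 4-fold H3K14ac had 211667. At 2-fold with a prior count of 5 it had 273639 of 394426 (69.4%), a fall that the range of 1.5 times counts as the same. Among identifiers with 1 region the enriched ones were 651 (H3K9ac), 3838 (H3K18ac), 1181 (H3K23ac), 13908 (H3K27ac), 2866 (H4K8ac), 894 (H2AK5ac) and 2446 (H3K4me3). For these marks they were 83.1% (H3K9ac) to 98.9% (H3K27ac) of the identifiers with 1 region that were tested. Median log2 ratios moved by 1.69 for H3K14ac and -1.19 for H3K9ac under TMM, with the calls kept within 1.5 times in number.

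For peak lists per gene, wider peaks gave 5.47 for arterial genes, 5.20 for the cystine list and 5.70 for lymphatic genes. The 1 kb window gave 6.40 for lymphatic genes and 6.39 for deacetylases. Gene spans gave 4.95 for lung epithelium, 4.57 for leukocytes, 7.67 for acetyltransferases, 7.72 for deacetylases and 7.38 for glycolysis. Unmatched random lists moved the call at 3.74 for lung epithelium, 3.78 for neurons, 6.56 for deacetylases and 6.44 for glycolysis. Folds at gene ends moved to 2.47 (H3K14ac-rich), 7.26 (H3K23ac-rich) and 8.30 (H3K4me3-rich) with wider peaks.

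Correlations moved to 0.028 (acetylations) and -0.130 (marks with IgG) with a minimum of 100 reads, over 2768 regions. With every library thinned to the shallowest they were -0.0026 (acetylations), -0.148 (with H3K4me3) and -0.117 (with IgG). Percentiles of the endothelial list in placeable reads were 97.7 (H3K14ac), 100 (H3K23ac) and 100 (H3K4me3) over gene bodies with 2 kb either side. They were 93.8 (H3K18ac), 37.9 (H3K27ac, turned) and 1.62 (H3K4me3) matched on the 9-library mean, 90.1 (H3K27ac) at 1 kb, and 6.91 (H3K4me3 specificity, 1.87 with the mean) with the median of the other marks. The latter says little, since the median gene had 0 H3K4me3 reads. Pairs of list and mark above random lists were 5 matched on the 9-library mean and 29 over gene bodies. The random lists for gene bodies were not matched on gene length, so length may enter their percentiles. Depth limits IgG most, at 365999 reads, where 1 read is 2.73 CPM.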

Other observations

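Several gene groups carried more peak bases inside the gene than random lists did, and the groups were not tested against each other. More than 2 kb inside the gene, H3K27ac-rich peaks covered 1605 bp per endothelial identity gene ± 2019 (SD over 32 genes), against 780 bp in random lists matched on gene length, and 1647 bp ± 2126 per venous gene (10 genes), against 567 bp (percentile 98.8). Of the endothelial genes, 24 had such a peak. H3K4me3-rich peaks inside the gene covered 1217 bp per endothelial gene, against 357 bp (percentile 99.99). Immediate-early genes had 135 bp of H3K27ac-rich peaks, against 46.4 bp (percentile 98.4), and liver, pancreas and muscle genes had 0 bp in 20 genes. For H3K4me3-rich bases, immediate-early genes lay at percentile 99.89, venous genes at 99.78, angiogenic growth genes at 99.51, glycolysis genes at 98.86 and housekeeping genes at 96.35.

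The tests of 2 hypotheses on peaks inside genes, and those of minimum-width peaks, were set before their results were seen, and the others below after, as were the comparisons with IgG. It was a hypothesis that endothelial identity genes carry more H3K27ac-rich bases inside the gene than genes of like length, and their mean lay at percentile 99.39 of random lists. The same hypothesis for housekeeping genes was not borne out for H3K27ac-rich bases, with percentile 62.3. Internal peaks may mark enhancers or internal promoters. These were not told apart, since no strand or exon was used here.

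Cldn5, the tight-junction claudin of endothelium, had no peak of any list within 2 kb of its ends (gene ID 12741, chromosome 16, 18776847 to 18778262). It was chosen after its values were seen. The nearest peaks end at 18757698 and start at 18785623, a gap of 27.9 kb, longer than 99.6% of the gaps between merged regions on that chromosome (median 1.55 kb). The table also holds 25139 regions on sequences other than chromosomes 1 to 19, X and Y. Whether one of these holds a copy of this stretch, so that its reads map to both places, was not tested, and the gap is not evidence that the marks are absent.

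In 35244 identifiers every base is shared with another identifier, and all 9 libraries together hold 0 reads there, against 28350401 in the other 543221. This is what discarding reads that overlap several identifiers predicts. No read could be counted there whatever the marks, so whether these places carry little of them stays open. In identifiers with 1 region that share part of their bases, H3K27ac reads per kb of unshared bases were 1.93 times those of identifiers that share none, less than the 2.91 times of IgG, and H3K14ac had 0.639 times. The other 6 marks had 4.38 times (H3K18ac) to 13.3 times (H2AK5ac), and no biological explanation was tested.

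That each peak list was densest in a different library is a pattern that peak calling on the library of each mark could give. The test asked for a lead of at least 2 times over the second library in each list. The smallest was 1.95 times, for H3K27ac over IgG, so the test went against this explanation for that list. IgG had reads in 903 identifiers, and the simulated data held no library this uneven, so the error of that ratio is not known. Depth does not give the pattern, since 8 different libraries led in reads per kb, not the deepest alone. Among mark libraries alone the smallest lead over unshared bases was 2.38 times, and no biological explanation was tested.

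Of the 69183 peaks of the H2AK5ac-rich list, 76.1% had the minimum width, and the density over unshared bases corresponds to 168 reads for such a peak if it shared no base. Amplified copies of single background fragments are a candidate explanation, tested by whether such peaks lie at gene ends under 1.5 times as often as shifted ones. They lay there 2.97 times as often (lowest 2.74 over the shifted sets), which argues against evenly spread background as the whole cause. Background fragments that themselves gather at gene ends would give the same result, so this test cannot exclude them. IgG read shares at gene ends were 2.10 times those of the unshared bases, but 19 of the 278 placeable regions with IgG reads lay there, 1.22 times the share of all placeable regions (95% interval 0.744 to 1.87). Narrow sites of the mark (a fold 1.10 times that of wider peaks) stay open, as do copies of fragments from marked chromatin, which were not tested.

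On identifiers that lie on contigs alone (1324), IgG had 0.294% of its reads and the marks at most 0.134% (H3K9ac).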
